A study of Homo sapiens with 27 samples.

How the data were processed

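Small RNA was profiled in DKs-8, a human colon cancer cell line with wild-type KRAS, in a control (SC) and in 2 VAP-A knockdowns, labelled KD1 and KD2. The series title names VAP-A, an endoplasmic reticulum protein of membrane contact sites, and the ceramide transporter CERT in the making of RNA-containing extracellular vesicles. The sample titles name the compartments cell, MV and Exo, and the series design speaks of large and small extracellular vesicles. MV was taken to mean the large vesicles and Exo the small ones. The 27 libraries fall into 9 groups of 3. Cells were grown in DMEM with fetal bovine serum, vesicles were purified from serum-free conditioned medium, and RNA was extracted with QIAzol and the miRNeasy kit, per the labels' protocols. Groups were taken from the sample labels, and no library was left out.

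The authors deposited 1 table of 1517 mature human miRNAs by 27 libraries. Its values were expected counts, deposited without scaling to library size; 84.0% of the values were whole numbers, and the others held fractions, as reads split between annotations would give. Adapter trimming with cutadapt 1.18, the use of DESeq2 and genome build hg19 are stated per the submitters' processing notes. The aligner, the counting tool, the miRBase release and the meaning of the "+2" in the table's name are not given in the sources used here. Counts were rounded to whole numbers before each test. 0 miRNAs had no count in any library. The table holds no messenger RNA, so the knockdown of VAP-A itself could not be checked.

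Each compartment's 9 libraries were fitted together with edgeR 4.0.16 (R 4.3.3): TMM scaling, the filterByExpr filter on low counts, and the robust quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 on the adjusted value. Within each compartment KD1, KD2 and the mean of both were compared with SC, and KD2 with KD1. The 3 compartments of control cells were compared in a fit of the 9 SC libraries. Differences between compartments in the response to knockdown were tested as interactions in a fit of all 27 libraries. The filter left 332 miRNAs in cells, 78 in large vesicles and 141 in small vesicles, 120 in the control libraries and 164 in all libraries, which held 99.8%, 95.6%, 97.9%, 96.6% and 98.6% of the counts. Folds are log2 values with a standard error. In edgeR fits it was derived from the fold and the F statistic of the quasi-likelihood test. It is approximate and may be smaller than counting error where a group held few counts. These p-values measure only the spread between these samples. Both knockdowns were compared with the same 3 control libraries per compartment. Their shared chance values were simulated with 100 sets of unchanged groups in which the control libraries were drawn anew too.

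15 lists of miRNAs were fixed: the let-7 family; the miR-200 family; the miR-17-92 cluster and its paralogs; the MIR100HG and MIR99AHG clusters with their paralogs miR-99b and miR-125a, which lie in neither; miRNAs of the intestinal epithelium; colorectal cancer oncomiRs; blood cell and serum miRNAs; muscle, stroma and neuron miRNAs; entries overlapping other abundant non-coding RNA; the miR-320 family with mirtrons; regulators of cholesterol and lipid metabolism; the miR-371-373 cluster with the C19MC cluster; p53, hypoxia and stress responsive miRNAs; the miR-29, miR-15/16 and miR-30 families; and miRNAs followed in earlier work on colon cancer vesicles. Each list with at least 3 measured members was tested with camera (limma 3.58.1, preset correlation 0.01). The 226 tests were adjusted together. These lists, the comparisons, the model of each and all alternatives except those named as added were chosen before the data were examined.

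Named miRNAs follow a rule. In each comparison the rule takes the 10 largest changes in each direction among those past the threshold with a mean of at least 50 CPM (counts scaled to library size) in 1 of the groups. Where fewer than 5 passed, all of them and the 3 smallest p-values were taken. It adds the 5 most abundant miRNAs per compartment of SC, up to 4 passing members of each list by abundance (2 where none passed), and every member of the earlier vesicle list. The folds of list members are given only for the mean of both knockdowns and for the control compartments, a narrowing made after the values were seen. Any miRNA named outside the rule is marked as chosen after its values were seen. Pairs of names whose counts were nearly equal in total (a relative difference of at most 0.05 and at least 50 counts) share reads and are uncertain: miR-103a-3p and miR-103b, miR-122-5p and miR-3591-3p, miR-203a-3p and miR-203b-5p, miR-3065-5p and miR-338-3p, both arms of miR-423 and miR-3184, miR-365a-3p and miR-365b-3p, both arms of miR-371a and miR-371b, miR-374b-5p and miR-374c-3p, and miR-499a-5p and miR-499b-3p. The 2 arms of miR-486 lay outside that limit. Their counts ended in the same fraction in most libraries that held fractions of them (170.9 and 145.9 in KD1 cell replicate 2). They may thus share reads and count 1 signal as 2, which was seen only after the data were examined.

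Replicates of a group were compared by a chi-square test on miRNAs with at least 20 counts together. MV KD1 replicates 2 and 4 (chi-square per degree of freedom 1.18) and Exo SC replicates 1 and 2 (1.20) agree within sampling noise on that set. Over miRNAs with at least 100 counts the values were 1.50 and 1.55, above sampling noise. Each such pair counts as 1 replicate in a mean with its SD. In the fits, and so in the folds, p-values and calls, its libraries count as 2, except in the added fit with merged replicates. No label says whether replicates are independent. Where a group held 1 to 3 counts of a miRNA, the ratio of pooled counts per total miRNA counts is given with its exact (Clopper-Pearson) 95% interval. Where it held 0, or less than 1, the bound uses a floor of 3 counts over the group. Intervals and floors cover counting error only. The interval table, the count of list calls under each scaling the count of libraries in each direction and the mean counts in small vesicles were added after the data were seen. The simulation of shared chance values was corrected then too, to draw the control libraries.

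Alternatives were DESeq2 size factors (RLE), total counts without TMM, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, all 27 libraries in 1 fit, the 2 groups alone, the replicate number as a block, the table without the entries overlapping other non-coding RNA, and each replicate left out in turn. Added after seeing the data were fits without entries of GC-rich precursors (over 65% GC), without 4 cell libraries that held at least 20 counts of miR-451a, and with near-identical replicates merged. Precursor GC content came from GENCODE release 29, which uses another build (GRCh38) than the counts; 1515 of 1517 entries (99.9%) matched a precursor, and no coordinates were used. Statistics were tested on simulated counts with known folds. For KD1 against SC the test called 72.9% of 2-fold changes in cells (326 miRNAs, 0.576% of unchanged ones called), 89.1% in large vesicles (81 miRNAs, 1.35%) and 79.3% in small vesicles (140 miRNAs, 1.04%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.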

Results

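Small RNA was sequenced from DKs-8 colon cancer cells and from the large and small extracellular vesicles (EVs) they released, in control cells and in 2 VAP-A knockdowns (KD1 and KD2). Each of the 9 groups had 3 libraries. VAP-A is a tether of endoplasmic reticulum contact sites, and the series asks how its loss alters the RNA that vesicles carry. Cell libraries held 319336 to 524977 miRNA counts, large EV libraries 4939 to 11683 and small EV libraries 14520 to 53584. Depth differed by group in the small EVs, with 14520 to 16183 counts in control libraries, 28862 to 53584 in KD1 and 21334 to 37673 in KD2. Each library detected 621 to 789 miRNAs in cells, 176 to 244 in large EVs and 285 to 439 in small EVs. A single control line was compared with both knockdown lines. Knockdown of VAP-A cannot be checked in a table of miRNAs. miR-10a-5p, which is encoded in a HOX gene cluster, had the highest share in all 3 control compartments. It took 31.7% ± 0.837 (SD, n = 3) of counts in cells and 25.1% ± 1.90 (SD, n = 3) in large EVs. In small EVs it took 17.5% ± 0.918 (SD, n = 2, a near-identical pair counted as 1). In control cells miR-26a-5p (5.59% ± 0.377, SD, n = 3), the oncomiR miR-21-5p (5.59% ± 0.802), miR-92a-3p (3.92% ± 0.0998) and let-7f-5p (3.48% ± 0.169) followed. In large EVs they were miR-6087 (14.2% ± 1.52, SD, n = 3), miR-7704 (5.18% ± 0.805), let-7i-5p (3.40% ± 0.248) and miR-26a-5p (3.39% ± 0.0428). In small EVs they were miR-7704 (9.70% ± 0.0630, SD, n = 2), the liver and gut lipid regulator miR-148a-3p (7.36% ± 0.201), miR-21-5p (4.39% ± 0.268) and miR-6087 (4.37% ± 0.126).

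Large EVs of control cells differed from the cells in most miRNAs tested. Of 120 miRNAs, 41 were higher and 49 lower. Among the highest were miR-7704 (log2 9.98 ± 0.15, SE, 3 against 3 libraries, a fold of 1013), miR-7641 (9.0 ± 0.47), miR-3168 (7.78 ± 0.21) and, further down, miR-6087 (5.47 ± 0.10, a fold of 44.2). All 6 measured entries overlapping other abundant non-coding RNA were higher, among them miR-4508 (6.86 ± 0.22) and miR-4488 (6.43 ± 0.17). The list test called them too (camera adjusted p = 0.0138; adjusted p = 0.501 with an estimated correlation). All 4 measured members of the miR-320 family, which is processed without Drosha, were higher, from 1.15 ± 0.17 for miR-320a to 5.15 ± 0.55 for miR-320d. The MYC-driven miR-17-92 family was lower in large EVs in all 5 measured members (4 with RLE factors). Among them were miR-20a-5p at -3.77 ± 0.38, miR-17-5p at -3.53 ± 0.41 and miR-93-5p at -2.88 ± 0.33. The 4 measured miR-200 miRNAs, guardians of epithelial identity, were lower, such as miR-429 (-1.64 ± 0.22). So were all 6 of the miR-29, miR-15/16 and miR-30 families, such as miR-29a-3p (-1.49 ± 0.18). The let-7 family, which restrains RAS and growth, was split, with 5 of 8 higher (let-7b-5p 1.19 ± 0.10) and 2 lower. miR-103a-3p and miR-103b, which share reads, stood at -3.59 ± 0.36. miR-30a-5p, with 2 counts in the large EV libraries against 1699 in cells, was 17.2-fold lower (95% interval 4.76 to 142). miR-548av-5p, with 1.65 counts in cells, was 920-fold higher (195 to 6596).

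The other lists were mixed in large EVs against cells. Lower were 5 of 6 cholesterol and lipid regulators (miR-27b-3p -1.83 ± 0.19 and miR-148a-3p -0.72 ± 0.09) and none was higher. Of 4 blood cell and serum miRNAs 3 were higher, with the red cell miRNA miR-451a at 5.41 ± 0.71, and 1 was lower. miR-451a had only 2 or 3 counts per large EV library and 2 to 4 per cell library here. Of 5 oncomiRs 3 were higher and 2 lower (miR-222-3p 1.69 ± 0.19, miR-221-3p -1.37 ± 0.19, products of the same cluster). Of 5 intestinal miRNAs 1 was higher and 2 lower (miR-10b-5p -1.36 ± 0.14; 0 and 2 with total counts). Of 4 in the list of the MIR100HG and MIR99AHG clusters, which also holds their paralogs miR-99b and miR-125a of another cluster, 1 was higher (miR-100-5p 0.90 ± 0.19) and 1 lower (miR-99a-5p -1.60 ± 0.34). Of 4 stress miRNAs 1 was higher and 2 lower (miR-146a-5p -1.78 ± 0.25). miR-372-3p, of the stem cell cluster miR-371-373, was higher (1.05 ± 0.27). Of 5 miRNAs followed in earlier work on colon cancer EVs 3 were higher (let-7a-5p 0.56 ± 0.08, whose call ended without a filter or with the 10 CPM filter, miR-100-5p and miR-320a) and 2 lower (miR-10b-5p and miR-21-5p, at -0.90 ± 0.12). The miR-7704 change had an adjusted p of 5.75e-21 by edgeR's quasi-likelihood test, in 3 of 3 libraries. Of the 90 called miRNAs 87 lay beyond the cell mean in all 3 large EV libraries, a tally that calling on these same libraries favours. In 86 of them the groups did not overlap. Leaving out 1 library ended list calls: large EV replicate 2 those of miR-200c-3p (-0.30), miR-92a-3p (-0.24) and miR-30d-5p (-0.44), replicate 4 that of miR-196a-5p (0.57), and any of the 3 that of let-7f-5p (0.04, -0.20 and -0.10 without replicates 2, 3 and 4). Replicates 2 or 4 ended those of miR-126-3p (-0.45 and -0.90) and miR-30c-5p (-0.24 and -0.48), each of the 3 that of miR-25-3p (-0.35 to -0.12), each of 5 libraries of both compartments that of miR-27a-3p (-0.42 to -0.21), and each of all 6 that of miR-10a-5p (-0.18 to -0.04, and 0.13 without large EV replicate 2). Camera called no other list here. The calls came to 136 without a filter on low counts and 146 with the 10 CPM filter, and the median log2 fold was -0.20, -0.04 with RLE factors and -0.36 with total counts.

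Small EVs of control cells also stood apart from the cells, with 37 of 120 miRNAs higher and 51 lower. miR-7704 (10.59 ± 0.15, a fold of 1539) and miR-4497 (8.22 ± 0.19) were among the highest, as were miR-451a (8.98 ± 0.23, a fold of 506) and miR-486-5p (6.30 ± 0.42), both abundant in red blood cells. The miR-451a fold rested on 2 to 4 counts per control cell library, against 49.1 to 65 per small EV library, so its size is uncertain. The 4 measured miR-320 members were higher, miR-320a by 2.12 ± 0.14 and miR-320d by 5.99 ± 0.33. The list was called (camera adjusted p = 0.0182; adjusted p = 0.727 with an estimated correlation). miR-148a-3p, which targets the LDL receptor, was higher in small EVs (1.14 ± 0.08), opposite to its direction in large EVs, and stood 1.86 ± 0.09 above large EVs. Lower were miR-103a-3p and miR-103b (-2.28 ± 0.25), miR-484 (-1.98 ± 0.27), miR-615-3p (-1.96 ± 0.24) and miR-10a-5p (-0.99 ± 0.07). All 5 measured miR-17-92 members were lower, such as miR-92a-3p (-0.63 ± 0.08), and all 4 miR-200 miRNAs (miR-200b-3p -0.73 ± 0.12). All 6 of the miR-29, miR-15/16 and miR-30 families were lower (miR-30d-5p -1.36 ± 0.16), or 5 with total counts. Of the blood list 3 of 4 were higher, and of the entries overlapping other non-coding RNA 5 of 6, with miR-4488 at 3.39 ± 0.19.

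The let-7 family gave 2 higher and 3 lower of 8 in small EVs against cells (let-7b-5p 0.44 ± 0.10, let-7a-5p -0.64 ± 0.08). Lipid regulators gave 1 higher and 4 lower of 6, and intestinal miRNAs 1 and 3 of 5 (miR-10b-5p -1.04 ± 0.13). OncomiRs gave 2 and 1 of 5 (miR-222-3p 0.87 ± 0.18; miR-21-5p -0.53 ± 0.11). The MIR100HG and MIR99AHG clusters gave 0 and 2 of 4 (miR-99b-5p -1.16 ± 0.22) and stress miRNAs 1 and 2 of 4. miR-372-3p was higher (1.57 ± 0.19). Of the earlier EV list 1 of 5 was higher (miR-320a) and 3 were lower, and miR-100-5p stood at 0.33 ± 0.17 (adjusted p = 0.0921). The miR-451a change had an adjusted p of 4.31e-18 in edgeR. All 88 called miRNAs were beyond the cell mean in 3 of 3 libraries, which the calling favours, and in 85 the groups did not overlap. Leaving out 1 small EV library ended list calls of miR-200c-3p (-0.21) and miR-196b-5p (-0.42) for replicate 1, miR-183-5p (0.38) for replicate 2, miR-200a-3p (-0.19 and -0.26) and miR-429 (-0.24 and -0.37) for replicates 1 or 2, miR-210-3p (-0.73 and -0.67) for replicates 1 or 3, and miR-99a-5p (-0.65 to -0.58) for each of the 3. Those of miR-29a-3p (-0.34 to -0.15), miR-30e-5p (-0.71 to -0.29) and miR-146a-5p (-0.38 to -0.19, and 0.00 without small EV replicate 3) ended without single libraries of either compartment. Camera called no other list here. The calls came to 141 without a filter on low counts and 145 with the 10 CPM filter, limma-voom ended the call of miR-21-5p, and total counts moved the median log2 fold from -0.19 to -0.05.

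Between the EV types of control cells, 38 of 120 miRNAs were higher in small EVs and 35 lower. miR-451a stood 3.57 ± 0.31 higher in small EVs (a fold of 11.9), and miR-148a-3p, miR-3182 (2.62 ± 0.39) and let-7a-3p (2.23 ± 0.65) were higher too. The large EV libraries held only 2 or 3 counts of miR-451a each. miR-20a-5p (2.50 ± 0.45), miR-17-5p (2.08 ± 0.50) and miR-93-5p (1.92 ± 0.39) made 3 of 5 miR-17-92 members higher, calls that limma-voom ended. Large EVs held more miR-6087 (-1.99 ± 0.09), miR-4488 (-3.04 ± 0.17), miR-7641 (-3.57 ± 0.44), miR-3168 (-2.55 ± 0.20) and let-7d-3p (-2.40 ± 0.26). Of the let-7 family 6 of 8 were lower in small EVs and 1 higher (let-7a-5p -1.20 ± 0.09, let-7b-5p -0.75 ± 0.11; 4 lower with total counts). Of the entries overlapping non-coding RNA 4 of 6 were lower. Near the count floor, miR-30a-5p was 8.22-fold higher in small EVs (95% interval 2.07 to 71.4). miR-663a, with less than 1 count there, was at least 10.4-fold lower.

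The remaining lists gave, higher and lower in small against large EVs, 2 and 0 of 4 miR-200 miRNAs (miR-429 1.09 ± 0.25), 3 and 0 of 4 blood miRNAs, and 2 and 0 of 4 in the miR-320 family (miR-320a 0.97 ± 0.17). Next came 3 and 2 of 6 lipid regulators (miR-128-3p -0.77 ± 0.15, a call that limma-voom ended), 1 and 2 of 5 intestinal miRNAs (miR-10a-5p -0.81 ± 0.07; 2 and 1 with total counts) and 2 and 2 of 5 oncomiRs (miR-221-3p 1.15 ± 0.20; 2 and 1). There were 0 and 2 of 4 in the MIR100HG and MIR99AHG clusters (1 and 1 with total counts), 3 and 1 of 4 stress miRNAs (miR-146a-5p 1.4 ± 0.28), and 2 and 2 of 5 of the earlier EV list (miR-10b-5p 0.32 ± 0.16, adjusted p = 0.0847). The miR-29, miR-15/16 and miR-30 families gave 2 and 2 of 6, 3 and 2 adjusted over the list alone, and 4 and 0 with total counts. miR-372-3p stood at 0.51 ± 0.27 (adjusted p = 0.105). The edgeR adjusted p of miR-451a was 1.01e-08. All 73 called miRNAs were beyond the large EV mean in 3 of 3 libraries, which the calling favours, and in 70 the groups did not overlap. Leaving out single libraries of either EV type ended calls of let-7i-5p (-0.19 to -0.05), let-7f-5p (-0.18 to -0.06), miR-100-5p (-0.50 to -0.32), miR-99b-5p (-0.77 to -0.65), miR-196b-5p (-0.59 to -0.38), miR-183-5p (-0.47 to -0.17), miR-486-5p (0.85 to 1.51) and miR-30c-5p (-0.74 to -0.71). Large EV replicate 2 ended that of miR-126-3p (0.82), replicate 3 those of miR-27a-3p (0.50) and miR-185-5p (1.82), replicate 4 that of miR-210-3p (1.76), and small EV replicate 3 those of miR-222-3p (-0.39) and miR-30d-5p (-0.46). Camera called no list. With total counts the split was 59 higher and 24 lower, as that scaling moved the median log2 fold from 0.10 to 0.41.

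Loss of VAP-A went with a large change of the miRNA profile in cells. Of 332 miRNAs, 100 rose and 120 fell in the mean of both knockdowns, 105 of them by more than 2-fold. The stem cell cluster miR-371-373, an oncogenic cluster of embryonic and germ cell tumours, rose as a group. Its 5 measured entries were all higher. miR-372-3p went from 686 ± 35.5 CPM (SD, n = 3) in control cells to 11162 ± 576 in KD1 and 11049 ± 1333 in KD2 (log2 4.02 ± 0.14, SE, a fold of 16.2). Others were miR-371a-3p (3.72 ± 0.24), miR-373-3p (3.64 ± 0.26) and miR-371a-5p (3.32 ± 0.17), with miR-371b entries that share reads with miR-371a. The cluster passed the list test (camera adjusted p = 1.57e-08; adjusted p = 0.165 with an estimated correlation), and miR-372-3p was higher in 6 of 6 knockdown libraries (edgeR adjusted p = 6.82e-17). miR-3168 rose by 2.41 ± 0.31 and miR-10a-5p by 0.84 ± 0.13. miR-10a-5p took 31.7% ± 0.837 of counts in control cells, 40.6% ± 1.05 in KD1 and 39.7% ± 1.98 in KD2. These shares are not TMM-scaled and rose by less than its fold. TMM factors were 1.22 to 1.31 in control cells and 0.736 to 0.944 in knockdown cells.

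The miRNAs that fell furthest in cells included miR-218-5p, which lies in introns of the SLIT genes, from 2562.0 ± 137 CPM (SD, n = 3) to 144 ± 13.6 in KD1 and 145 ± 36.9 in KD2 (log2 -4.15 ± 0.13, SE). miR-99a-5p, a repressor of mTOR, fell by 3.28 ± 0.14, and so did miR-129-5p (-4.08 ± 0.29), miR-598-3p (-3.86 ± 0.31), miR-296-3p (-3.77 ± 0.26) and miR-455-5p (-3.39 ± 0.30). Others fell nearly to the counting floor. miR-342-3p was 107-fold lower in KD1 (1 count, 95% interval 18.9 to 4270). In KD1 miR-618 was 42.0-fold lower (2 counts, 11.3 to 351) and miR-708-5p 40.1-fold lower (12.7 to 186). miR-296-5p was 106-fold lower in KD2 (1 count, 18.6 to 4223). The miR-17-92 cluster and its paralogs fell as a group, with 11 of 12 measured members lower and 0 higher under each scaling (camera adjusted p = 0.0283; adjusted p = 0.733 with an estimated correlation, and adjusted p = 0.0570 without control replicate 3). Its examples were miR-20a-5p (-1.62 ± 0.14), miR-17-5p (-1.32 ± 0.15) and miR-92a-3p (-0.48 ± 0.12). The share of miR-92a-3p went from 3.92% ± 0.0998 of counts to 1.90% ± 0.0712 in KD1 and 2.09% ± 0.0631 in KD2. That is a larger fall than its fold, since shares are not TMM-scaled. Of the miR-29, miR-15/16 and miR-30 families 6 of 11 fell and 0 rose, among them miR-30a-5p (-3.24 ± 0.14) and miR-30b-5p (-1.28 ± 0.16).

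The let-7 family rose in cells in 8 of 9 members, with let-7i-5p at 0.99 ± 0.14, let-7a-5p at 0.98 ± 0.14 and let-7f-5p at 0.79 ± 0.14. The other fell (camera adjusted p = 0.0800; 7 rose with total counts). Of 10 oncomiRs 7 rose and 1 fell (miR-222-3p 1.19 ± 0.11, miR-183-5p 0.93 ± 0.14, miR-182-5p 0.83 ± 0.13; 4 and 2 with total counts). miR-21-5p stood at 0.08 ± 0.12 (adjusted p = 0.550), -0.42 with total counts. Of 5 miR-200 miRNAs 3 rose (miR-200b-3p 0.77 ± 0.12), but the median of the family turned from 0.41 to -0.08 with total counts, which left 1 higher. In the list of the MIR100HG and MIR99AHG clusters 2 of 6 were higher and 3 lower (3 and 3 adjusted over the list alone). miR-100-5p, of MIR100HG, rose by 0.95 ± 0.14. The falls were of miR-99a-5p, of MIR99AHG, and of the paralogs outside both clusters, miR-99b-5p (-1.98 ± 0.12) and miR-125a-5p (-1.26 ± 0.12). Of 7 intestinal miRNAs 2 rose and 2 fell (miR-10b-5p -2.04 ± 0.13, miR-194-5p -0.77 ± 0.13; 1 and 5 with total counts). Of 10 p53, hypoxia and stress miRNAs 3 rose and 4 fell, among them the hypoxia marker miR-210-3p (-2.35 ± 0.15). Of 8 lipid regulators 3 rose and 4 fell (miR-128-3p 0.60 ± 0.14; 0 and 5 with total counts). The neuronal miR-9 arms fell (miR-9-5p -2.38 ± 0.15, miR-9-3p -2.83 ± 0.39), 2 of 3 in the list of muscle, stroma and neuron miRNAs. In the miR-320 list 3 of 5 rose and 1 fell (miR-320a 0.77 ± 0.12; 1 and 1 with total counts). Of 11 entries overlapping non-coding RNA 4 rose and 2 fell (miR-4488 1.93 ± 0.17, miR-663a 2.01 ± 0.27; 3 and 4 with total counts). Of the earlier EV list 3 of 6 rose (let-7a-5p, miR-100-5p and miR-320a) and miR-10b-5p fell. miR-125b-5p stood at 0.32 ± 0.15 (adjusted p = 0.0709), -0.16 with total counts. Without control replicate 2 the calls of the intestinal miR-196a-5p (0.24 ± 0.14) and of miR-877-5p, the fall in the miR-320 list (-0.53 ± 0.25), ended, the latter also without KD2 replicate 2 (-0.45 ± 0.22). Camera called neither these lists nor the let-7 family.

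Of 7 blood cell and serum miRNAs 4 rose in cells and 1 fell (miR-126-3p -1.04 ± 0.14), but the rise came from some of the libraries. Both miR-486 arms, which may share reads, are among the 4. miR-451a had 79.1, 72.1 and 94.1 counts in the KD1 libraries and 55.3 in KD2 replicate 2, against 0 and 2.11 in KD2 replicates 3 and 4 and 2 to 4 in control cells. Its log2 fold of 4.49 ± 1.45 (edgeR adjusted p = 0.0307, 5 of 6 libraries above the control mean) and that of miR-486-5p (3.76 ± 1.38, adjusted p = 0.05, 4 of 6) did not pass when any KD1 or control library was left out (4.30 ± 1.84 to 4.94 ± 1.97 and 3.36 ± 1.69 to 4.07 ± 1.86), and miR-486-5p stood at -0.93 without the 4 libraries. A fit without those 4 libraries, added after the data were seen, called 182 miRNAs, 88 higher and 94 lower. In it the calls of miR-92a-3p and other weak changes ended. That fit kept only KD2 replicates 3 and 4 as knockdown libraries, so the loss of libraries alone could end such calls. Of the 220 calls, 208 lay beyond the control mean in all 6 libraries, which the calling favours, and in 184 the groups did not overlap. With total counts 48 rose and 166 fell in the mean of both knockdowns, since that scaling moved the median log2 fold from -0.08 to -0.57. The fit of all 27 libraries tested fewer miRNAs and called 118.

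In large EVs, whose depth allowed 78 miRNAs to be tested, 5 were higher and 11 lower in the mean of both knockdowns (8 and 11 with total counts), and 2 of them moved by more than 2-fold. miR-372-3p rose from 1756 ± 570 CPM (SD, n = 3) in control EVs to 6448 in KD1 and 6420 in KD2 (log2 1.86 ± 0.20, a fold of 3.64), the direction it took in cells. miR-7704 (0.73 ± 0.15), miR-221-3p (0.81 ± 0.19) and miR-27a-3p (0.70 ± 0.17) rose, and miR-21-5p by 0.28 ± 0.10. miR-3168 fell by 1.3 ± 0.15, the reverse of its rise in cells. miR-10b-5p (-0.81 ± 0.14), let-7d-3p (-0.74 ± 0.18), let-7b-5p (-0.49 ± 0.10), miR-423-5p (-0.67 ± 0.15) and miR-6087 (-0.45 ± 0.13) fell too, with miR-3184 entries that share reads with miR-423. miR-92a-3p (-0.38 ± 0.09) was the 1 of 2 measured miR-17-92 members that fell. By list, higher and lower, the let-7 family gave 0 and 1 of 8 (let-7a-5p -0.13 ± 0.09), miR-200 0 and 0 of 4 (miR-200c-3p -0.06 ± 0.11, 0.03 with total counts, under which 1 member of the family rose), and MIR100HG and MIR99AHG with paralogs 0 and 1 of 2 (miR-99b-5p). Next were intestinal miRNAs 0 and 1 of 5 (0 and 2 adjusted over the list alone), oncomiRs 2 and 0 of 5, lipid regulators 1 and 0 of 5, and stress miRNAs 0 and 0 of 2 (1 and 0 adjusted over the list alone, with RLE factors or with total counts, miR-146a-5p 0.83 ± 0.32). The rest were the non-coding RNA entries 0 and 0 of 4 (miR-4488 -0.33 ± 0.17), the miR-320 family 0 and 0 of 3 (miR-320a 0.16 ± 0.13), the miR-29, miR-15/16 and miR-30 families 0 and 0 of 3, and the earlier EV list 1 and 1 of 5 (miR-100-5p 0.14 ± 0.17, -0.04 without control replicate 2). No member of the blood list could be tested in the large EV fit, and none of the muscle, stroma and neuron list in either EV fit or in the control fit. The miR-372-3p rise passed edgeR's test at an adjusted p of 8.28e-07 in 6 of 6 libraries, as did miR-3168 at 1.16e-06. In only 8 of the 16 calls did the knockdown and control libraries not overlap. Single libraries carried some calls: without control replicate 4 those of miR-221-3p (0.66 ± 0.23), let-7d-3p (-0.63 ± 0.21) and miR-92a-3p (-0.27 ± 0.10) ended. The call of miR-99b-5p ended without control replicate 3 or 4, KD1 replicate 1 or 4 or KD2 replicate 3 (-0.84 ± 0.33 to -0.71 ± 0.36). Without control replicate 2 or 3 so did those of miR-6087 (-0.36 ± 0.15 and -0.42 ± 0.16) and miR-21-5p (0.28 ± 0.12 and 0.30 ± 0.11), and the last also without KD2 replicate 3 (0.26 ± 0.11). KD2 alone gave 12 calls, but 4 without control replicate 3, control replicate 4 or KD2 replicate 4, 6 without KD2 replicate 2, 4 without a filter and 5 with DESeq2.

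In small EVs 33 of 141 miRNAs were higher and 25 lower in the mean of both knockdowns, 19 of them by more than 2-fold. The greatest losses were of miR-3182 (-2.78 ± 0.20) and of miR-6087, which went from 44256 ± 1244 CPM (SD, n = 2) in control EVs to 7652 ± 506 in KD1 and 7662 ± 893 in KD2 (log2 -2.54 ± 0.07, a fold of 0.172). miR-4492 (-2.46 ± 0.30), miR-3656 (-2.42 ± 0.19), miR-3195 (-1.71 ± 0.21) and the hypoxia marker miR-210-3p (-1.70 ± 0.44) fell. So did the red cell miRNAs miR-451a (-1.4 ± 0.14), miR-486-5p (-1.34 ± 0.23) and miR-486-3p (-1.32 ± 0.26, possibly from reads shared with miR-486-5p), 3 of the 5 blood miRNAs measured. Their mean counts per library stood at 0.858, 0.880 and 0.893 of those in control EVs while the libraries were 2.31 times as deep, against 0.394 for miR-6087 and 0.338 for miR-3182. Of the stem cell cluster, with 2 members measured and so no list test, miR-372-3p rose by 1.85 ± 0.13 (a fold of 3.60). So did miR-371a-5p by 1.73 ± 0.45 (a call that ended without control replicate 2) and, from shared reads, miR-371b-3p by 1.79 ± 0.45. let-7d-3p rose by 1.11 ± 0.18, miR-328-3p by 1.92 ± 0.63, miR-548av-5p by 1.59 ± 0.51 and miR-615-3p by 0.85 ± 0.23. miR-99a-5p, which fell in cells, rose by 0.84 ± 0.20.

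In small EVs the miR-17-92 cluster split, with miR-92a-3p (0.36 ± 0.05) and miR-25-3p (0.49 ± 0.09) higher and miR-17-5p (-0.84 ± 0.17) and miR-20a-5p (-0.82 ± 0.14) lower among 5 measured. Of the let-7 family 4 of 8 rose and 0 fell (let-7a-5p 0.36 ± 0.07, let-7d-5p 0.66 ± 0.13). miR-148a-3p fell by 0.46 ± 0.05 while miR-128-3p (0.59 ± 0.10) and miR-27a-3p (0.49 ± 0.11) rose, so that 2 of 7 lipid regulators were higher and 1 lower. Higher and lower were 1 and 2 of 4 miR-200 miRNAs (miR-200c-3p 0.39 ± 0.10, miR-200a-3p -0.61 ± 0.13), 2 and 0 of 5 in the MIR100HG and MIR99AHG clusters, and 2 and 0 of 6 intestinal miRNAs (miR-10a-5p 0.46 ± 0.06). There were 1 and 0 of 7 oncomiRs (miR-183-5p 0.44 ± 0.11) and 1 and 2 of 4 entries overlapping non-coding RNA (miR-4488 0.49 ± 0.15, miR-4508 -1.25 ± 0.16). There were 0 and 2 of 4 in the miR-320 family (miR-320a -0.27 ± 0.08), 0 and 1 of 3 stress miRNAs and 3 and 1 of 6 in the earlier EV list. The miR-29, miR-15/16 and miR-30 families gave 1 and 0 of 7, and 0 and 0 adjusted over the list alone. miR-125b-5p (-0.11 ± 0.36) and miR-21-5p (0.04 ± 0.05) did not pass, and each took the other sign under some settings. Camera called no list in either EV type for the mean of both knockdowns.

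The miR-6087 loss had an edgeR adjusted p of 1.33e-15, in a fit that counts the near-identical control libraries separately. All 58 called miRNAs of small EVs lay beyond the control mean in 6 of 6 libraries, which the calling favours, and in 51 the groups did not overlap. Knockdown libraries were deeper than control ones. Single control libraries carried some calls. They ended for miR-371a-5p without control replicate 2 (1.08 ± 0.41), for miR-615-3p (0.50 ± 0.24) and miR-320a (-0.19 ± 0.09) without replicate 3, for miR-200c-3p without replicate 1 (0.20 ± 0.10). They ended for miR-183-5p without replicate 1 or 3 (0.32 ± 0.13 and 0.25 ± 0.12), for miR-328-3p without replicate 1 or 2 (1.31 ± 0.67 and 1.68 ± 0.77), and for miR-548av-5p (1.25 ± 0.60 to 1.69 ± 0.69) and miR-4488 (0.37 ± 0.19 to 0.47 ± 0.19) without any of the 3; DESeq2 ended those of miR-328-3p and miR-548av-5p. Likewise ended miR-100-5p without any of the 3 (0.25 ± 0.14 to 0.33 ± 0.15), miR-30d-5p without any of the 3, KD1 replicate 2 or KD2 replicate 1 (0.29 ± 0.18 to 0.43 ± 0.17), let-7g-5p without control replicate 2 (0.20 ± 0.10), miR-429 without replicate 3 (-0.35 ± 0.15), and miR-320b without control replicate 3, KD1 replicate 3 or KD2 replicate 3 (-0.34 ± 0.14 to -0.25 ± 0.11).

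The calls of the 2 knockdowns overlapped in each compartment. In cells 181 of 332 were called in both with the same sign, in large EVs 11 of 78 and in small EVs 40 of 141, and 0 with opposite signs. Independent lists would share 63.8, 1.38 and 8.72. Simulated unchanged groups with shared controls had 0 in common by edgeR in 100 simulations (at an unadjusted p under 0.05 they shared 3.09, 0.75 and 1.82 on average, and the real ones 186, 16 and 60). With no miRNA changed, such groups give few adjusted calls, so the 0 was nearly fixed in advance. The simulation also cannot tell an effect of both knockdowns from a difference of the single control line. Camera called the miR-371-373 list in KD1 and in KD2 cells (adjusted p = 1.20e-09 in each; adjusted p = 0.165 with an estimated correlation). In KD2 cells it also called the miR-17-92 list (adjusted p = 0.0182; adjusted p = 0.729 with an estimated correlation) and the let-7 family (adjusted p = 0.0317; adjusted p = 0.827 with an estimated correlation). KD1 alone gave 92 higher and 109 lower in cells, 6 and 10 in large EVs and 27 and 25 in small EVs. KD2 alone gave 95 and 114, 3 and 9, and 27 and 20 (with total counts 49 and 149 for KD1 in cells, 43 and 163 for KD2 in cells, and 5 and 3 for KD2 in large EVs; 5 and 7 there with RLE factors). miR-372-3p rose by 4.02 ± 0.15 in KD1 cells and 4.01 ± 0.15 in KD2 cells, miR-218-5p fell by 4.15 ± 0.17 and by 4.14 ± 0.17, and in small EVs miR-6087 stood at -2.54 ± 0.08 and -2.54 ± 0.09. Across miRNAs, which are not independent replicates, the correlation of the log2 folds was 0.950 in cells, 0.854 in large EVs and 0.965 in small EVs (0.420, 0.472 and 0.675 simulated). The covariance was 2.1, 0.212 and 0.593 against 0.0488, 0.0342 and 0.0610 simulated, a difference of 2.05, 0.178 and 0.532. The comparisons share their control libraries, which are too few to split, so part of the excess may come from them.

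**Figure D1:**
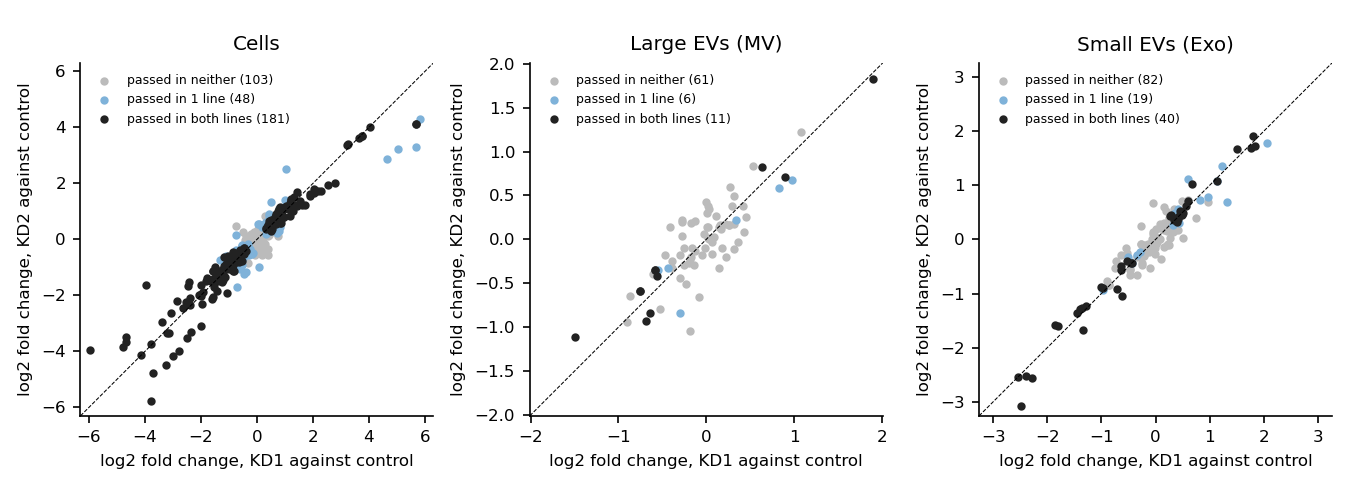
Log2 fold of KD1 against control (x axis) and of KD2 against control (y axis) for each miRNA tested in cells, large EVs and small EVs, 1 point per miRNA. Both knockdowns passed the test with the same sign for 181, 11 and 40 miRNAs and with opposite signs for 0.

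Compared directly, KD2 and KD1 differed in 0 miRNAs in any compartment by edgeR's quasi-likelihood test, by DESeq2 and by limma-voom, with 2 in large EVs when all 27 libraries were fitted together and with 24, 4 and 8 at an unadjusted p under 0.05 in edgeR in cells, large EVs and small EVs. The smallest p-values were those of miR-1287-5p (1.21 ± 0.39, edgeR adjusted p = 0.486), miR-181a-3p (0.92 ± 0.30) and miR-7704 (-0.58 ± 0.20) in cells. In large EVs they were miR-191-5p (-0.43 ± 0.14, adjusted p = 0.414), miR-151a-3p (-0.47 ± 0.18) and miR-200b-3p (-0.28 ± 0.13), and in small EVs miR-615-3p (0.51 ± 0.16, adjusted p = 0.366), miR-92a-3p (0.16 ± 0.05) and miR-224-5p (0.73 ± 0.25). In cells camera called the let-7 family (adjusted p = 0.0234; adjusted p = 0.827 with an estimated correlation), but adjusted p = 0.756 without KD2 replicate 4 and adjusted p = 0.0828 without KD1 replicate 4, in runs added after the data were seen. KD2 replicate 4 stood apart, with 18.4% of counts in the let-7 family against 15.9% and 16.3% in the other KD2 libraries and 14.6% to 15.6% in KD1, and a TMM factor of 0.736 against 0.930 and 0.944. Camera also called the blood list (adjusted p = 0.000184, and adjusted p = 0.718 with an estimated correlation), which counts both miR-486 arms, though no member passed by itself. The number of calls in cells was 8 without KD2 replicate 2, the KD2 library that held miR-451a.

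**Figure D2:**
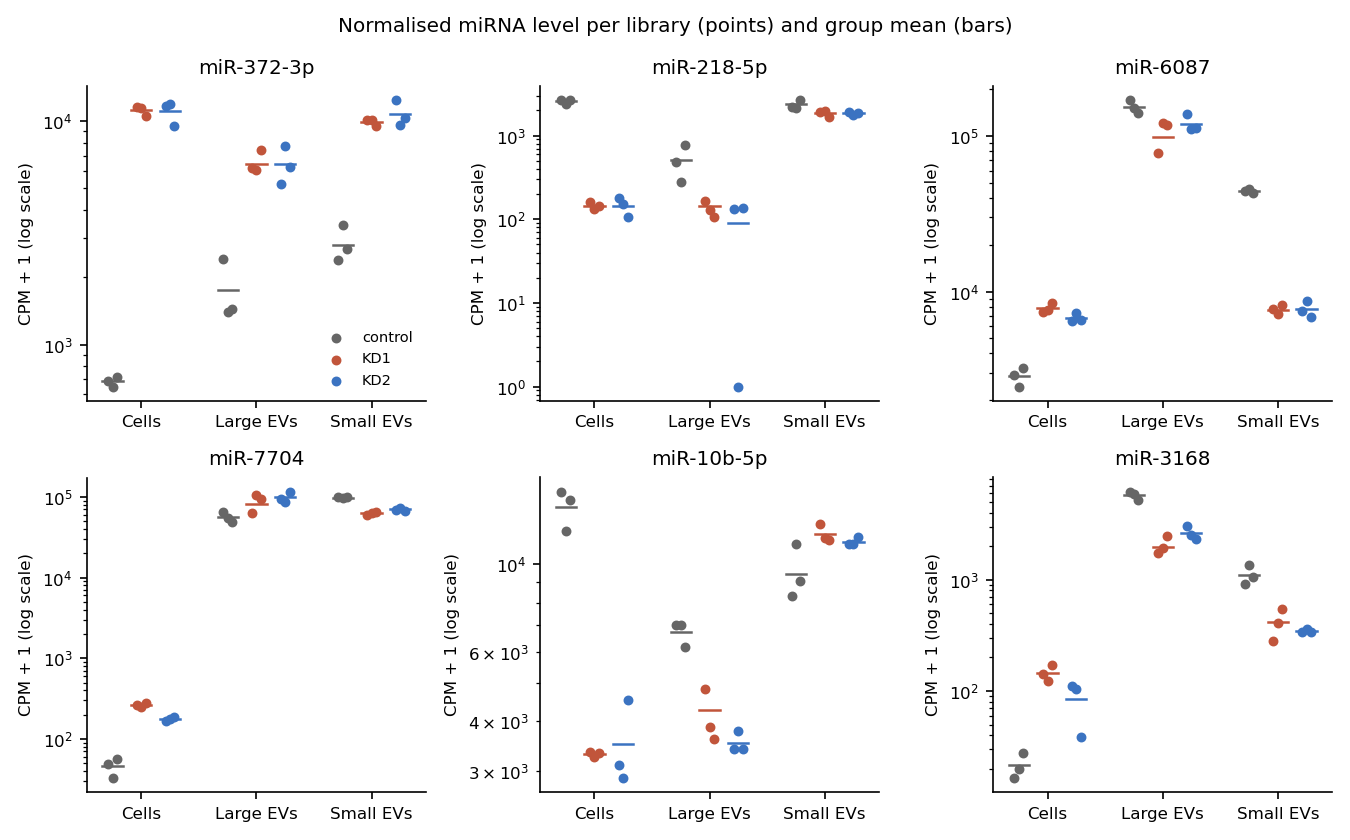
CPM of single miRNAs in each library, on a log axis, by compartment and group, with 1 point per library. miR-372-3p rose in every compartment, whereas miR-218-5p fell from 2562.0 to 144 CPM in KD1 cells and stood at 1863 CPM in KD1 small EVs against 2396 in control small EVs.

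The response to knockdown differed between compartments. In small EVs against cells 38 miRNAs had a more positive and 37 a more negative response among 164 tested together (59 and 27 with total counts, which moved the median difference from 0.09 to 0.36). miR-99a-5p had fallen in cells and risen in small EVs (difference 4.32 ± 0.30, edgeR adjusted p = 2.64e-14), and miR-10b-5p likewise (2.54 ± 0.15). The small EV rise of miR-10b-5p, 0.29 ± 0.09, did not pass without control replicate 1 (0.11 ± 0.11), control replicate 3 (0.20 ± 0.11), KD2 replicate 1 (0.23 ± 0.10) or KD2 replicate 2 (0.24 ± 0.10). miR-218-5p fell in cells but stood at -0.33 in small EVs (difference 4.01 ± 0.21, adjusted p = 1.75e-17). miR-6087 had risen in cells and fallen in small EVs (difference -3.69 ± 0.16, adjusted p = 4.79e-19), as had miR-3168 (-3.73 ± 0.44), miR-3195 (-3.26 ± 0.37) and miR-3656 (-3.22 ± 0.30). In large EVs against cells 35 responses were more positive and 32 more negative (47 and 22 with total counts, median difference 0.27), among them miR-3168 (-3.39 ± 0.39) and miR-20a-5p (2.3 ± 0.54). The let-7 family was called in that comparison, with 7 of 9 responses more negative in large EVs than in cells (camera adjusted p = 0.0172; adjusted p = 0.727 with an estimated correlation; 1 more positive and 5 more negative with total counts). Camera called no other list between compartments. In small against large EVs 19 responses were more positive and 22 more negative, such as let-7d-3p (1.73 ± 0.26), miR-10b-5p (0.97 ± 0.20) and miR-6087 (-2.20 ± 0.16). That number of calls, 41, came to 26 without a filter on low counts, 25 by limma-voom and 21 without entries of GC-rich precursors.

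Of the 139 miRNAs tested in both cells and small EVs, 50 passed in both, 25 with the same sign and 25 with opposite signs, where independent lists would share 44.7 (Fisher's exact test, 2-sided, p = 0.0354). Across those miRNAs, which are not independent replicates, Pearson's r of the log2 folds was -0.0473 and Spearman's rho 0.0517. miR-372-3p rose in both, while miR-99a-5p, miR-10b-5p and miR-6087 took opposite signs. Cells and large EVs shared 11 of 76, 7 of them with the same sign (12.6 for independent lists, p = 0.305 by the same exact test), and the EV types shared 11 of 77, 4 of them with the same sign (8.94, p = 0.273 by the same exact test). The share of all counts taken by each list was compared in 90 exact permutation tests, and 0 had an adjusted p under 0.05 (smallest 0.107, for a smallest unadjusted p of 0.0119 that the 84 splits of the cell libraries allow).

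**Figure D3:**
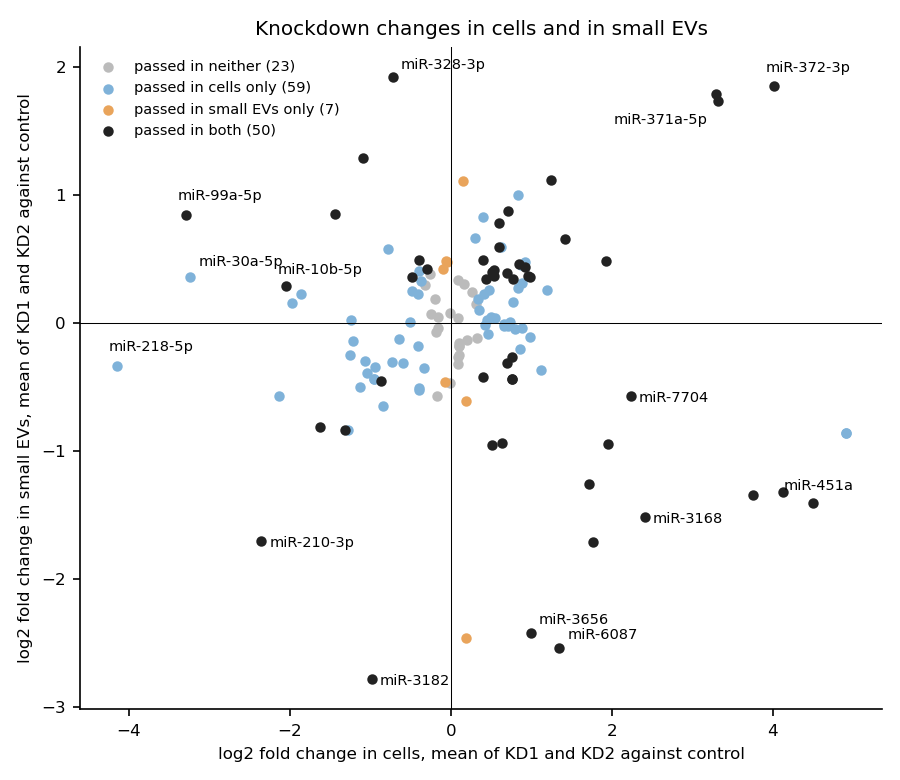
Log2 fold of the mean of both knockdowns against control in cells (x axis) and in small EVs (y axis), 1 point per miRNA tested in both. Of 139 miRNAs, 50 passed in both, 59 in cells only and 7 in small EVs only.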

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

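Every test of an explanation here was chosen after its result was seen, except the counts from other splits of the unmerged libraries and the count of small EV reads behind the second pattern; parts of a pattern were set after its whole was tested.

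The first pattern is the loss of 9 GC-rich entries from small EVs on knockdown. miR-6087, miR-4492, miR-3656, miR-3195, miR-210-3p, miR-4508 and 3 others (miR-4634, miR-4497 and miR-7704, chosen after their values were seen) passed as lower, all from precursors over 65% GC. A GC bias between libraries stays open. Of the 12 tested entries at least as GC-rich as the least GC-rich of these, 9 were lower and 1 higher (miR-4488, a call that single control libraries ended). That cut was set by the lower entries, so all 9 lie within it by construction. Of all 21 tested entries over 65% GC, 9 were lower, 6 higher and 6 did not pass. Their median log2 fold was 0.15, against 0.02 at or under the limit, where Spearman's rho of GC content and fold was -0.0224. GC-rich entries thus did not fall as a set. The 5 others that rose lay nearer the limit (from 67.2% GC), and the precursor is a proxy for the reads. A fixed background in deeper libraries is argued against for miR-6087 and miR-3656, whose counts per library fell to ratios of 0.394 and 0.420 with every knockdown library below every control library. It stays open for miR-4492, miR-3195 and miR-210-3p (ratios 0.409 to 0.721, libraries overlapping), for the other 4 (0.954 to 1.54) and so for the sum (1.16), and neither a background that differs between libraries nor a VAP-A effect was tested apart from these.

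The second pattern is the 27 miRNAs that fell in cells, did not pass as lower in small EVs and differed between the compartments by the interaction test, such as miR-218-5p. miR-103a-3p and miR-103b, which share reads, count as 2 of them. The pattern shows 1 side only: among all 164 miRNAs tested, 38 responses were more positive in small EVs than in cells and 37 more negative. Reads of a red cell source in the EVs are argued against, since the nearer of miR-451a and miR-486-5p, which fell in small EVs, lay -4.99 standard errors from the median (-0.22) of all 42 miRNAs that fell in cells and were tested there. Of the same blood list, miR-126-3p (-0.39 ± 0.23), which belongs to the pattern, and miR-122-5p (-0.86 ± 0.44) lay within 2 standard errors of that median. Another blood or serum source thus stays open. Too few reads to show a fall as large as in cells are argued against, since all 27 stood over 2 standard errors above their cell fold. The choice by the interaction test favours this, and these standard errors are approximate. Without that choice, 38 of the 42 lay above their cell fold (median -0.22 against -0.95). A smaller fall may still be hidden, as in miR-218-5p (-0.33 ± 0.13), since the median member had 16.2 counts per control small EV library, under the 20 set beforehand, and a VAP-A effect on which miRNAs leave the cell stays open, untested.

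The third pattern is miR-451a and miR-486-5p in 4 of the 6 knockdown cell libraries. A response to the knockdown is argued against as the whole cause, since 2 knockdown libraries, KD2 replicates 3 and 4, held no more miR-451a than control cells. Carry-over from the small EV libraries is argued against by miR-7704, whose ratio to miR-451a reached at most 0.0462 of that in control small EVs. For RNA of blood cells of several types, 3 of 11 other blood list members had at least 10 counts in KD2 replicate 2 and under 10 in the other KD2 libraries. They were miR-486-5p, miR-486-3p and miR-122-5p, and the 2 miR-486 arms may share reads. This count cannot decide the question. miR-126-3p, with 158 and 92 counts in KD2 replicates 3 and 4, could not meet that rule. With 55.3 counts of miR-451a in KD2 replicate 2, scarcer blood miRNAs may not reach 10. Serum of the growth medium, which could bring red cell miRNAs and the liver miRNA miR-122-5p, stays open and was not tested.

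Other splits of the same libraries were counted for each number of calls. For the mean of both knockdowns against control, 1 of 100 splits of the cell libraries gave as many calls (220, highest other 109). So did 2 of 100 of the small EV libraries (58, highest other 63) and 4 of 100 of the large EV libraries (16, highest other 18). Few splits reached the real numbers, and each share lay under the limit set beforehand for arguing against chance. In both EV types another split gave more calls, though, so chance is not taken as excluded there. In cells the real split gave the most calls, which speaks against chance only if the libraries are independent. For the differences between compartments, 1 of 100 splits gave as many in large EVs against cells (67, highest other 65). So did 2 of 100 in small EVs against cells (75, highest other 75) and 1 of 100 in small against large EVs (41, highest other 10). Splits that mix the groups do not keep the knockdown change within each compartment, so no conclusion on chance is drawn for the differences. With near-identical replicates merged, 1 of 100 splits gave as many in large EVs (22, highest other 21) and 3 of 100 in small EVs (61, highest other 72). For each difference between compartments 1 of 100 did (66, 78 and 36, highest other 65, 73 and 20), with the same limit. Chance is not excluded by these counts either. In small EVs another split again gave more calls, and in large EVs the highest other came close. The other comparisons set 3 libraries against 3, which allows 10 splits, too few for a statement on chance. For KD1 and KD2 against control in each compartment and for the control compartments, 1 of the 10 gave as many, with the real numbers 201, 209, 16, 12, 52, 47, 90, 88 and 73 and a highest other of 0; KD2 against KD1 gave 0 calls, which 10 of 10 splits reach (highest other 1 in large EVs and 0 in cells and small EVs).

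The interaction test named 67 miRNAs whose response to knockdown differed between large EVs and cells (SE of each difference 0.226 to 2.3). More positive in large EVs were miR-374b-5p and miR-374c-3p (difference 8.92), miR-30a-5p (4.62), miR-210-3p (3.57), miR-185-5p (2.98), miR-101-3p (2.84), miR-99a-5p (2.68), miR-140-3p (2.43), miR-3182 (2.42) and miR-20a-5p (2.3). More negative were miR-4473 (-5.98), miR-486-3p (-5.72), miR-486-5p (-5.20), miR-122-5p and miR-3591-3p (-4.89), miR-3168 (-3.39), miR-371a-5p (-2.48), miR-371b-3p (-2.37), miR-663a (-2.23) and miR-4488 (-1.93). Several rest on counts near the floor: in control large EVs miR-374b-5p had 0 counts (7.5 in the knockdowns, at least 1.41-fold higher), miR-30a-5p and miR-210-3p 2 (2.25-fold higher in the knockdowns, 95% intervals from 0.449 to 21.7), miR-185-5p 2 (4.78-fold, 1.13 to 42.6), miR-101-3p 2 (2.61-fold, 0.523 to 24.1) and miR-140-3p 3 (3.0-fold, 0.858 to 16.1). In KD1 large EVs miR-4473 had 0 counts (11 in control and 4 in KD2), so its difference gives no size, and miR-486-3p, miR-486-5p and miR-122-5p had 2. In cells miR-122-5p had 1 count in the control and 62 in the knockdowns (34.3-fold, 5.94 to 1378). The differences of these blood miRNAs rest on the 4 cell libraries that held miR-451a: without them those of miR-486-3p (-0.94 ± 1.31) and miR-486-5p (-0.55 ± 1.33) did not pass, and miR-122-5p was not tested.

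The same test named 75 miRNAs between small EVs and cells (SE 0.15 to 1.25). More positive in small EVs were miR-99a-5p (4.32), miR-218-5p (4.01), miR-30a-5p (3.81), miR-548av-5p (2.95), miR-328-3p (2.88), miR-548k (2.56), miR-10b-5p (2.54), miR-615-3p (2.49) and miR-374b-5p and miR-374c-3p (2.42). More negative were miR-451a (-5.59), miR-486-3p (-5.19), miR-122-5p and miR-3591-3p (-5.03), miR-486-5p (-4.85), miR-1248 (-3.89), miR-3168 (-3.73), miR-6087 (-3.69), miR-3195 (-3.26) and miR-3656 (-3.22). miR-548av-5p had under 3 counts in cells on both sides, so its fold there is not given, and miR-1248 had 2 in small EVs of each knockdown. Without the same 4 cell libraries the differences of miR-451a (-0.59 ± 2.79), miR-486-3p (-0.49 ± 1.175) and miR-486-5p (-0.30 ± 1.204) did not pass either, and miR-122-5p was not tested.

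Between small and large EVs the test named 41 miRNAs (SE 0.14 to 1.96). More positive in small EVs were miR-663a (7.49), miR-4473 (7.37), miR-328-3p (2.49), miR-130b-5p (1.87), let-7d-3p (1.73), miR-16-2-3p (1.69), miR-615-3p (1.39), miR-10b-5p (0.97), miR-99b-5p (0.96) and miR-423-3p (0.82). More negative were miR-3182 (-4.02), miR-4492 (-3.03), miR-1248 (-2.80), miR-3656 (-2.56), let-7a-3p (-2.26), miR-4497 (-2.21), miR-6087 (-2.20), miR-3195 (-2.04) and miR-103a-3p and miR-103b (-1.45). In small EVs miR-663a had under 1 count in the control (at least 1.89-fold higher in the knockdowns) and miR-4473 had 2 (5.62-fold higher, 95% interval 1.48 to 47.6), beside 0 in KD1 large EVs.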

How the results depend on the processing

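The alternatives were chosen before the results were seen, except the fits without GC-rich precursors, without the 4 cell libraries that held miR-451a, with near-identical replicates merged, and the list tests without single libraries. Of 7491 alternative values of named miRNAs, 6888 kept their direction and their side of the threshold, 522 no longer passed, 42 newly passed and 39 took the other sign. Depth limits large EVs most, with 78 miRNAs testable.

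Numbers of calls that moved by over 1.5 times were, with all 27 libraries in 1 fit, 112 for KD1, 115 for KD2 and 118 for their mean in cells, where fewer miRNAs were tested, and 2 for KD2 against KD1 in large EVs. For KD2 in large EVs they were 4 without a filter, 5 with DESeq2 and 4 to 12 over single libraries left out. For KD2 against KD1 in cells the range was 0 to 8. Without a filter and with the 10 CPM filter, which test more miRNAs, control large EVs against cells gave 136 and 146 and small EVs 141 and 145. Small against large EV responses gave 26 without a filter, 25 by limma-voom and 21 without GC-rich precursors. Of 226 list tests camera called 11, 17, 18 and 17 without control small EV replicates 1, 2 and 3 (10 to 15 without other libraries), 0 with an estimated correlation, 12 with RLE factors and 14 with the block, and fry, which asks another question, 111. The replicate number as a block moved no number of calls by over 1.5 times, such as 201 against 201 for KD1 in cells. The median correlation of same-numbered libraries was 0.0951 in cells, -0.0824 in large EVs, 0.00729 in small EVs and -0.0477 in the control libraries. The numbers thus showed no clear pairing in the EVs or the control libraries. In cells most same-numbered pairs were positive (-0.0167 to 0.277) and most others negative, so a weak pairing there stays open. Median, mean and camera direction differed in sign, in lists not called, for the earlier EV, miR-320 and lipid lists in large EVs after knockdown and the miR-17-92 and miR-29, miR-15/16 and miR-30 lists in small EVs. They did so in control small EVs for oncomiRs (against cells), stress miRNAs (against large EVs) and the earlier EV list (both). Between compartments they did so for miR-200 (large EVs against cells), stress and earlier EV miRNAs (small EVs against cells), and the miR-17-92, non-coding RNA, lipid, stress, miR-29, miR-15/16 and miR-30, and earlier EV lists (small against large EVs). Merging near-identical replicates gave 22 calls in large EVs and 61 in small EVs for the mean of both knockdowns; leaving out the 4 miR-451a libraries gave 182 in cells, 61 for large EVs against cells and 64 for small EVs against cells.

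Values that took the other sign follow; beyond fewer libraries or entries in a fit, the cause was not tested. In cells with total counts they were miR-429 (-0.0784), miR-196a-5p (-0.17), miR-221-3p (-0.0272), miR-27a-3p (-0.0762), miR-125b-5p (-0.16) and miR-21-5p (-0.42). miR-21-5p also stood at -0.16 without a filter and -0.24 with all 27 libraries, and miR-486-5p at -0.93 without the 4 libraries. In large EVs miR-200c-3p stood at 0.0333 with total counts, 0.0234 without GC-rich precursors and 0.0197 with merged replicates (-0.0824 to 0.0199 over single libraries left out), miR-4508 at 0.00823 with the block (-0.19 to 0.0775), miR-200b-3p at -0.0236 to 0.15 and miR-100-5p at -0.0371 to 0.34. In small EVs miR-125b-5p stood at 0.00241 without a filter, 0.00476 by limma-voom and -0.56 to 0.29 over single libraries left out, and miR-21-5p at -0.0687 with all 27 libraries, -0.0671 with merged replicates, -0.0370 without the non-coding RNA list, -0.0249 without GC-rich precursors and -0.0835 to 0.0567 over single libraries. In control large EVs against cells miR-10a-5p stood at 0.0231 without the non-coding RNA list, 0.0516 without GC-rich precursors and -0.18 to 0.13 over single libraries, and let-7f-5p at -0.24 to 0.0402. In control small EVs miR-146a-5p against cells ranged from -0.39 to 0.00198, let-7i-5p against large EVs stood at 0.0168 with total counts and 0.0332 with the 10 CPM filter, and let-7f-5p at 0.0556, 0.0766 with the 10 CPM filter and 0.0125 without one.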

Other observations

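The test of both arms of a precursor was chosen before its result was seen; its counts in large and small EVs, of precursors with 1 arm past the threshold and without miR-371b and miR-486 were added after.

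Where both arms of a precursor passed in knockdown cells, they mostly moved together. Of 72 precursors with both arms tested, 30 had both arms past the threshold, and in 27 of them (90%) the arms took the same sign, such as both arms of miR-296 and of miR-9, which fell. Without miR-371b, which shares reads with miR-371a, and miR-486, whose rise came from some libraries and whose arms may share reads, these were 25 of 28. In 26 others 1 arm alone passed, and in 17 of these the other arm had the same sign, such as miR-340 (-2.14 and -0.30, chosen after its values were seen). Over all 72 precursors, which are not independent replicates, the arms had the same sign in 50, and Pearson's r between their folds was 0.842 and Spearman's rho 0.638. A change in the level of some precursors may thus underlie part of the changes in cells, beside changes of single arms; this is a hypothesis that the counts of mature miRNAs cannot take further. In large EVs the only such precursors, miR-423 and miR-3184, share their reads. In small EVs 2 of 3 had arms of the same sign, 1 of them miR-486, too few to weigh.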
